A study of Mus musculus with 24 samples.

How the data were processed

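RNA of the distal and proximal ends of the mandible and the maxilla of mouse embryos at embryonic day 12.5 was hybridised, as biotin-labelled cRNA, to 24 single-colour expression arrays with 45101 probe sets. Per the series text, the knockout embryos lack Tgfbr2 in Wnt1-Cre cells, and littermates served as controls, whose genotype is not given in the sources used here. The deposited table gives log2 signal, which the authors computed by RMA per the submitters' processing notes. The version of the RMA software is not given in the sources used here. Values lay between 2.97 and 14.70, with 0 missing, and array medians lay between 7.26 and 7.38. The smallest root mean square difference between 2 arrays was 0.171, so no array was a copy of another.

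Probe sets were named by the platform annotation and their Entrez numbers were matched to a mouse gene table. Of the probe sets, 34945 had 1 gene symbol, 932 with several symbols, 9160 with none and 64 controls were left out. Each of the 18193 genes was represented by its probe set with the highest mean, and 9010 genes had more than 1. A gene was tested if it lay above the 30th percentile of its array (5.85 to 5.93) in at least 3 arrays, which kept 14879 genes. No further normalisation was applied.

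Arrays were grouped by genotype, jaw and end as the labels give them, in 8 groups of 3. Limma fitted 8 group means to all 24 arrays, with 16 residual degrees of freedom, and tested contrasts by its two-sided moderated test with the default prior. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, separately for each comparison, and an adjusted p under 0.05 was called. The comparisons were knockout against control as the mean over the 4 regions and in each region, the difference of that effect between jaws and between ends, mandible against maxilla in controls, distal against proximal in each control jaw, and the difference of the last between jaws. In the mandible against maxilla comparison positive changes are higher in the mandible, and in comparisons of ends positive changes are higher distally. Whether the array numbers pair arrays across groups was checked by correlating deviations from group means. The median correlation was 0.15 for the same genotype and number and 0.03 for the same number with another genotype and region. This did not settle whether the numbers pair arrays, and no pairing was used. Arrays with the same genotype and number do share some signal, such as that of Y-linked genes. The main test takes them as independent all the same, so its p-values can be too small.

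The genes named were set by a rule. For the knockout comparison over the regions it takes Tgfbr2, then the 10 largest rises and the 10 largest falls among the genes called that moved the same way in all 4 regions, then up to 4 called members of each list. For each single region and each difference of effects it takes the 4 largest rises and falls. For the control comparisons it takes the 10 largest each way and up to 4 called members of each list, and where fewer than 5 genes pass, those with the smallest p up to 5. Genes named beyond this rule were chosen after their values were seen, among them Mpg, Rian, Hoxd1, Ednrb, Nhlh2 over the regions, Sncg in the difference between jaws and list members given as examples without having passed over all genes.

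The 28 gene lists covered TGF-beta response genes, TGF-beta ligands, receptors and Smads, BMP, Hedgehog, Wnt and FGF signalling, the cell cycle, p53, hypoxia and glycolysis, immediate early genes, sterol and lipid metabolism, and extracellular matrix. They also covered markers of cartilage, bone, tendon, skeletal muscle, epithelium, neurons, glia and Schwann cells, endothelium, erythroid cells, macrophages, and eye and forebrain, Hox genes of the second arch and behind, mandibular and maxillary identity, and distal and proximal jaw genes. Some genes stand in more than 1 list, such as 7 of the mandibular identity and 7 of the distal jaw genes. Lists were tested by camera with its preset correlation of 0.01, adjusted over the lists, and again by camera with an estimated correlation and by fry, which asks whether a list's genes move one way and compares them with no other genes. A list score of an array is the mean deviation of its genes from their mean over the 24 arrays.

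Groups, tests, lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were centring of array medians, cyclic loess, no filter or a filter at the 50th percentile (12252 genes), the mean of all probe sets or each probe set singly, a prior with trend and robust estimation, array weights, a fold threshold of 1 (log2), only the groups compared, the array number as a fixed or random block or as 6 means, and leaving out each array. A further 4 alternatives, which leave out sets of arrays, were chosen after the data were seen. The fit was tested on simulated data, with 200 of 14879 genes changed by log2 0.5, 1 or 2. For the knockout comparison over the regions it recovered 85.1%, 97.0% and 100% of them with 5 unchanged genes called, and for maxilla proximal 56.7%, 91.0% and 95.5% with 13. The simulated noise was normal and independent between genes and arrays. It held no signal shared between arrays and no array unlike its group, so these rates do not carry over to the real arrays. Computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.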

Results

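RNA from the jaws of mouse embryos at embryonic day 12.5 was measured on 24 single-colour arrays. The labels give 2 genotypes, controls and knockouts in which Wnt1-Cre was used to delete a floxed Tgfbr2 gene. Wnt1-Cre is active in neural crest cells, which form most of the facial mesenchyme, and Tgfbr2 encodes the type II receptor for TGF-beta. From each genotype the mandible and the maxilla were taken, and each jaw was divided into a distal and a proximal end. The 8 groups held 3 arrays each, numbered 1 to 3, so 12 arrays carried each genotype. The median log2 value of an array lay between 7.26 and 7.38, and 14879 genes passed the filter on low values. The 30th percentile of an array lay between 5.85 and 5.93, and a change from or to a group value below it is a difference against background and so a lower bound. The labels do not say that the arrays of a group came from separate embryos, so every p-value here measures the spread between arrays only, and the test takes the arrays as independent. The number of arrays limits the precision of all values. Changes are log2 differences with their standard error (SE), and group values are means ± SD with n = 3 unless another n is given.

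Sex-linked genes and the likeness of arrays were checked first. Eif2s3y, a gene of the Y chromosome, lay between 10.2 and 10.4 in the 4 control arrays with number 2 and at 3.88 or below in the other 20 arrays. Xist, the RNA that coats the inactive X chromosome, was at 6.74 or below in those 4 arrays and at 13.6 or above in the others. All 12 knockout arrays and 8 of the control arrays therefore had Xist and no Y-linked signal. In 9 arrays the deviations from the mean of all arrays were, across genes, closer to the arrays of the other end of the same jaw than to their own group. For control maxilla 1 and knockout mandible 1 this held at both ends. The mean correlation was 0.54 with the own group and 0.81 with the other end for control maxilla proximal 1, and 0.36 against 0.81 for control maxilla distal 1. It was 0.33 against 0.67 for knockout mandible distal 1 and 0.44 against 0.54 for knockout mandible proximal 1. The other arrays were control maxilla distal 2 (0.58 against 0.68) and 3 (0.58 against 0.61), knockout mandible distal 2 (0.55 against 0.63), knockout mandible proximal 3 (0.59 against 0.67) and knockout maxilla proximal 3 (0.20 against 0.33). Without the 4 arrays of control maxilla 1 and knockout mandible 1, control maxilla distal 2 and 3 were closer to their own group (0.80 against 0.53 and 0.42). Knockout mandible distal 2 (0.61 against 0.64), knockout mandible proximal 3 (0.64 against 0.64) and knockout maxilla proximal 3 were not. All arrays were kept in their labelled groups. Counts without the 4 arrays of control maxilla 1 and knockout mandible 1, called here the 4 arrays with doubted ends, stand beside the counts below where they differ by more than 1.5 times.

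The comparison of genotypes addresses what loss of TGF-beta reception in neural crest cells changes in the jaws. Tgfbr2 itself was not lower in the arrays labelled knockout. Its most highly expressed probe set had 11.78 ± 0.29 (SD, n = 12) in controls and 12.11 ± 0.40 (SD, n = 12) in knockouts, a difference of 0.34 (SE 0.11, adjusted p = 0.112). The differences were 0.39 in mandible distal, 0.31 in mandible proximal, 0.21 in maxilla distal and 0.43 in maxilla proximal. The other 2 probe sets differed by -0.05 and 0.05, and the first of these lay at background with a mean of 3.79, so its value is uninformative. Where these probe sets lie relative to the floxed part of the gene is not given in the sources used here.

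Averaged over the 4 regions, 42 genes were higher and 28 lower in the knockout arrays (limma, Benjamini-Hochberg adjusted p under 0.05), and 3459 genes had an unadjusted p under 0.05. The changes were small, with a median size of 0.40 among the genes called. H2az2, which encodes a histone variant of the H2A.Z family, fell by 0.57 (SE 0.043, adjusted p = 5.86e-07), and all 12 knockout arrays (12.69 to 13.19) lay below all 12 control arrays (13.47 to 13.65). The Wnt1-Cre transgene is known to be inserted at H2az2, so this fall may come from the transgene rather than loss of Tgfbr2. The genotype of the controls is not given in the sources used here. A transcript of unnamed function, 2610524H06Rik, rose by 0.63 (SE 0.047, adjusted p = 5.86e-07). Galc, the lysosomal galactosylceramidase, rose by 1.06 (SE 0.15, adjusted p = 0.00358). Mpg, a DNA glycosylase of base excision repair, rose by 0.39 and Rian, a long RNA of the imprinted Dlk1-Dio3 region, by 0.54, while Zfp33b fell by 0.49. These 6 genes were the ones called in each of the 24 fits that left out 1 array. They were also the only ones called with genotype and number as a random block, which allows for signal shared by arrays of a set. The other genes called, some of them named below, did not pass there. The array number as a fixed block gave more genes. The block of 6 means, which averages the regions of each genotype and number, called none, so these 6 genes did not pass either.

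Of the 70 genes, 58 moved the same way in all 4 regions. Among these the largest rises were those of Grik3, a kainate receptor subunit (1.31, SE 0.28, adjusted p = 0.042), Zfp804a (1.24), Galc, Cdh15, the cadherin of muscle precursors (1.02), and the small heat shock protein gene Cryab (0.95). Magel2 rose by 0.83, Barx2 by 0.73, Dgkk by 0.72 and Fibin by 0.66. The largest falls among the 58 were those of P4ha3, a subunit of collagen prolyl hydroxylase (-0.71, SE 0.14), H2az2, Eya1, a transcriptional coactivator of organ development (-0.53, SE 0.12, adjusted p = 0.0488), and Zfp33b. Adamts6 (-0.42), Slc25a35 (-0.41), Auts2 (-0.39), Pcgf5 (-0.38), Ccdc39 (-0.36) and Rasl11b (-0.36) fell too. The other 12 genes did not move the same way in all regions. Those with the largest changes were Hoxd1 (2.51), Nefl, a neurofilament subunit (1.67), Sncg, a synuclein of sensory neurons (1.22), Ednrb, the endothelin receptor of neural crest cells (1.05), and Cdh19, a cadherin of Schwann cell precursors (1.00), all with a negative change in mandible proximal. Without knockout mandible proximal 1, Hoxd1 had 0.18 and Cdh19 0.15 there, while Nefl (-0.68), Sncg (-1.49) and Ednrb (-0.09) stayed negative. The bHLH gene Nhlh2 (-1.26) was lower by 3.59 in mandible proximal and had 0.17 in maxilla proximal.

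This count rested on single arrays. It was 2132 without knockout maxilla proximal 3, 831 without knockout mandible distal 3, 518 without control mandible distal 2, 459 without knockout maxilla distal 3 and 334 without control maxilla distal 1. Without control maxilla proximal 1, 2 or 3 it was 12, 12 and 29, and without control maxilla distal 2 or 3 it was 6 and 8. Without control mandible proximal 1, 2 or 3 it was 6, 18 and 6, and without control mandible distal 1 or 3 it was 9 and 10. Leaving out knockout mandible distal 1 or 2 gave 10 and 20, knockout mandible proximal 1 or 3 gave 16 and 8, knockout maxilla distal 1 or 2 gave 7 and 7, and knockout maxilla proximal 1 or 2 gave 6 and 14. Without the 4 arrays with doubted ends 23 genes were called, and without the 4 arrays with Y-linked signal 20. Without knockout maxilla proximal 1 and 2, the 2 most neuron-rich arrays, 8 were called, and 15 without these and the arrays with doubted ends. Cyclic loess gave 164, the trend and robust prior 192, the stricter filter 258 and array weights 2906.

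**Figure D1:**
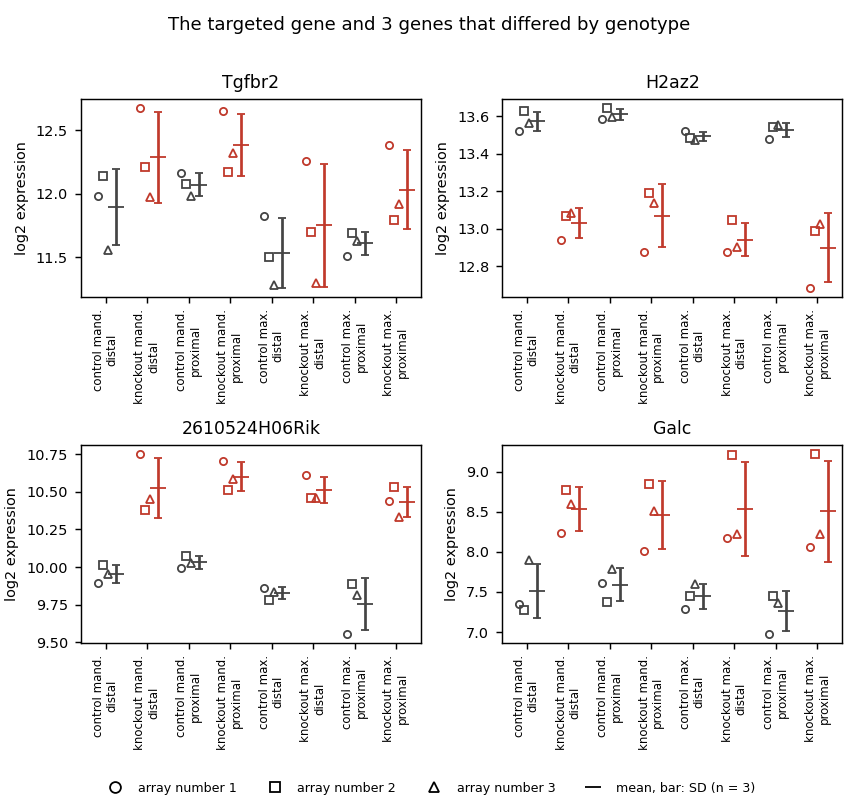
Log2 value of Tgfbr2, H2az2, 2610524H06Rik and Galc on each array (vertical axis) in the 8 groups (horizontal axis), controls in grey and knockouts in red, with circles, squares and triangles for arrays 1, 2 and 3 and bars for the mean ± SD (n = 3). H2az2 lies between 12.69 and 13.19 on all knockout arrays and between 13.47 and 13.65 on all control arrays, while Tgfbr2 is not lower in knockouts.

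Lists of genes fixed beforehand were compared with all other genes by camera, and 9 of 28 lists were called in the mean over the regions. None of the 9 was called with an estimated correlation between genes. Skeletal muscle genes were higher, with a median of 1.75 over 18 genes of which all had a positive change (adjusted p = 2.91e-13, and adjusted p = 0.358 with an estimated correlation). None of them passed over all genes and 17 passed adjusted over the list alone, such as Myh3 with 2.38 (SE 0.59), the titin gene Ttn with 2.25 and Myod1 with 1.62. The muscle median was 2.80 in mandible distal, 0.10 in mandible proximal, 1.17 in maxilla distal and 2.90 in maxilla proximal, and the list was not called in mandible proximal (adjusted p = 0.862). Glial and Schwann cell genes had a median of 0.59 with 7 of 7 positive (adjusted p = 5.11e-06, adjusted p = 0.272 with an estimated correlation). Cdh19 passed over all genes, and 7 passed adjusted over the list alone, among them Fabp7 with 1.10 and Sox10 with 0.49. The glial median in mandible proximal was -0.05 (adjusted p = 0.862). Genes of maxillary identity had a median of 0.41 with 10 of 10 positive (adjusted p = 0.00143, adjusted p = 0.358 with an estimated correlation). Adjusted over the list alone 5 of them were higher, among them Cyp26a1, which degrades retinoic acid, with 0.73 (SE 0.16) and Nr2f1 with 0.73, while their median in mandible proximal was -0.10 (adjusted p = 0.417). In controls this list did not set the maxilla apart and was not called between the jaws. Its mean score was 0.37 in control mandible proximal, 0.01 in maxilla proximal, -0.20 in maxilla distal and -1.06 in mandible distal. Its rise therefore does not show a shift toward the maxilla. Macrophage genes had a median of 0.32 (adjusted p = 0.000484, adjusted p = 0.703 with an estimated correlation), with 8 of 12 higher adjusted over the list alone, such as Ctss with 0.61 (SE 0.14). Immediate early genes had 0.22 (adjusted p = 0.00143, adjusted p = 0.410 with an estimated correlation), with 2 of 11 higher adjusted over the list alone. Extracellular matrix genes had 0.14 (adjusted p = 0.026, adjusted p = 0.724 with an estimated correlation) with 1 of 18, and Hox genes 0.34 (adjusted p = 0.0488, adjusted p = 0.703 with an estimated correlation) with 0 of 8. Cell cycle genes had -0.08 (adjusted p = 0.00249, adjusted p = 0.703 with an estimated correlation), with 3 of 17 lower adjusted over the list alone. Erythroid genes had -0.41 with 0 of 10 positive (adjusted p = 0.000484, adjusted p = 0.703 with an estimated correlation). The erythroid score was lowest in the knockout arrays with number 1, at -0.95, -0.85, -0.76 and -0.94. Apart from Cdh19, no member of these 9 lists passed over all genes.

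TGF-beta response genes were not called as a list, with a median of 0.03 over 19 genes (adjusted p = 0.541). Adjusted over the list alone, 6 were higher and 4 lower, while 0 passed over all genes by limma. The 6 were Acta2, smooth muscle actin, with 1.28, Ltbp2 with 0.51, Postn with 0.42, Bhlhe40 with 0.30, Cdkn2b with 0.24 and Junb with 0.22. The 4 were the tendon factor Scx with -0.42, the inhibitory Smad7 with -0.27, Tgif1 with -0.18 and Skil, a repressor induced by the pathway, with -0.11. TGF-beta ligands, receptors and Smads had a median of 0.05 (adjusted p = 0.521), and Tgfbr3, a coreceptor, had 0.48 and passed adjusted over the list alone. Median changes were -0.06 for BMP (adjusted p = 0.0822), -0.01 for Hedgehog (0.337), -0.20 for Wnt (0.112) and 0.06 for FGF genes (0.560). They were 0.01 for p53 targets (adjusted p = 0.542), 0.08 for hypoxia (0.0789), -0.05 for sterol synthesis (0.242), 0.16 for cartilage (0.345), 0.07 for bone (0.492) and 0.10 for tendon genes (0.611). Neuron genes had a median of 0.16 with 8 of 14 positive (adjusted p = 0.122), endothelial genes 0.04 (0.790) and eye and forebrain genes 0.18 (0.492). Genes of the distal jaw had -0.32 (adjusted p = 0.130), and genes of the proximal jaw had 0.19 (0.144), with Barx1 at 1.25, Dlx1 at 1.19 and Dlx2 at 0.83 passing adjusted over the list alone. The epithelium list had a median of -0.04, a mean of 0.05 and a test pointing down (adjusted p = 0.947). The list of mandibular identity had a median of 0.09, a mean of 0.03 and a test pointing down (adjusted p = 0.901).

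In mandible distal, 18 genes were higher and 2 lower in knockouts. Nr2f1, a nuclear receptor that controls pattern formation, rose by 2.79 (SE 0.48, adjusted p = 0.0169), from 9.08 ± 0.98 to 11.88 ± 1.12. Tcf21, a factor of branchial muscle precursors, rose by 2.78 (SE 0.46, adjusted p = 0.014), from 5.82 ± 0.90, a level at background, to 8.60 ± 0.77. Ms4a4d rose by 2.24 and Ccnb3 by 2.08, while H2az2 fell by 0.54 and H2aj, another H2A histone gene, by 0.52. Of 28 lists 11 were called, and none with an estimated correlation. Muscle genes had a median of 2.80 (adjusted p = 0.145 with an estimated correlation), with Tcf21 higher over all genes and 18 adjusted over the list alone. Glial genes had 1.13 (adjusted p = 0.0932 with an estimated correlation), with Erbb3, a neuregulin receptor, higher over all genes (1.13) and 5 adjusted over the list alone. Genes of maxillary identity had 0.97 (adjusted p = 0.0932 with an estimated correlation), with Nr2f1 and Nr2f2 (1.52) higher over all genes and 5 adjusted over the list alone. Hox genes had 0.87 (adjusted p = 0.360 with an estimated correlation), macrophage genes 0.47 (adjusted p = 0.566 with an estimated correlation), immediate early genes 0.27 (adjusted p = 0.145 with an estimated correlation) and FGF genes 0.21 (adjusted p = 0.499 with an estimated correlation). Genes of the distal jaw had -0.90 with 0 of 8 positive (adjusted p = 0.232 with an estimated correlation), among them Alx1, a homeobox gene of frontonasal mesenchyme, with -2.90 (SE 1.1), which did not pass. Without knockout mandible distal 1, an array with doubted ends, Alx1 had -1.2 and the list a median of -0.39 with 1 of 8 positive. Lower lists were also erythroid genes with -0.61 (adjusted p = 0.541 with an estimated correlation), Wnt genes with -0.45 (adjusted p = 0.660 with an estimated correlation) and BMP genes with -0.14 (adjusted p = 0.511 with an estimated correlation). Without knockout mandible distal 1 the medians were 0.55 for Hox, 0.14 for macrophage, 0.18 for immediate early, 0.35 for FGF, -0.21 for erythroid, -0.26 for Wnt and -0.06 for BMP genes. Without knockout mandible distal 3 they were 0.11 for FGF and 0.41 for immediate early genes. Except for FGF and macrophage genes, the lists called here also differed along the control mandible, and all moved toward its proximal end. The muscle score was -0.96 ± 1.66 in control distal, 1.80 ± 0.21 in control proximal and 1.76 ± 0.61 in knockout distal. The neuron score did not move so (-1.36, 0.65 and -1.07 in the same order). Both comparisons share the control mandible distal arrays, so they are not independent. Limma called 0 genes without control mandible distal 1 or 3 or knockout mandible distal 1 or 2 (1553, 1035, 917 and 1421 with an unadjusted p under 0.05). It called 180 without control mandible distal 2, 258 without knockout mandible distal 3, and 40 and 46 without knockout maxilla proximal 1 and 3. A fit of only these 2 groups called 0 (1437 unadjusted), and 13 were called without the 4 arrays with doubted ends, which include knockout mandible distal 1. Array weights gave 642 genes, and 62, 31 and 54 were called without the neuron-rich arrays, without these and the doubted ends, and without the arrays with Y-linked signal.

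In mandible proximal, neuron genes were lower in knockouts. Neurod1, a neurogenic factor, fell by 3.98 (SE 0.50, adjusted p = 0.00336), from 9.31 ± 0.55 to 5.33 ± 0.68, a level at background. Also lower were Nhlh2 (-3.59, SE 0.51), Pou4f1, a homeobox gene of sensory ganglia (-3.07, SE 0.48), and Ppp1r1c (-3.03, SE 0.51). The 2 genes that rose were 2610524H06Rik (0.57) and Mpg (0.41), against 6 that fell, and Mpg had -0.0086 as the mean of all its probe sets. The neuron list had a median of -1.23 with 0 of 14 positive and was called also with an estimated correlation (adjusted p = 0.0225). Pou4f1 was lower over all genes and 10 were lower adjusted over the list alone, such as peripherin, Prph, with -3.06, Ina with -2.72 and Stmn3 with -2.62. Epithelial genes had a median of 1.00 with 15 of 15 positive (adjusted p = 0.141 with an estimated correlation), with 4 higher adjusted over the list alone, such as the keratin gene Krt8 with 1.85, which had 0.94 without knockout mandible proximal 3. The epithelium scores of arrays 1, 2 and 3 were -0.58, -0.35 and -1.58 in controls and 0.42, -0.37 and 0.56 in knockouts. Control array 3 thus lowered the control mean, and knockout array 2 lay at the level of control array 2. Hypoxia genes had 0.15 with 13 of 13 positive (adjusted p = 0.141 with an estimated correlation). Extracellular matrix genes had 0.17, immediate early genes 0.04, cell cycle genes -0.07 and erythroid genes -0.28 (adjusted p = 0.683, 0.638, 0.683 and 0.683 with an estimated correlation). In the same order these medians were 0.05, 0.10, -0.02 and -0.02 without knockout mandible proximal 1, and the first 3 were 0.31, 0.09 and -0.11 without knockout mandible proximal 2. Centring array medians gave 0 higher and 6 lower, a fit of only these 2 groups called 0 (limma, 670 unadjusted), and 2 genes were called without the 4 arrays with doubted ends. Without the arrays with Y-linked signal limma called 0 (363 unadjusted), while 31 were called without the neuron-rich arrays and 294 with array weights. Limma called 0 genes without control mandible proximal 1 or knockout mandible proximal 3 (335 and 318 unadjusted). It called 1 without control mandible proximal 2, 2 without control mandible proximal 3, 1 without knockout mandible proximal 1, 17 without knockout mandible proximal 2 and 28 without knockout maxilla proximal 3.

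In maxilla distal, 3 genes passed the test. 2610524H06Rik rose by 0.68 (SE 0.093, adjusted p = 0.0116) and Rad51b, a gene of homologous recombination, by 0.61 (SE 0.097, adjusted p = 0.0275), while H2az2 fell by 0.55 (SE 0.085, adjusted p = 0.0275). Genes of the proximal jaw were higher as a list, with a median of 1.01 and 10 of 11 positive (adjusted p = 0.117 with an estimated correlation), among them Barx1 with 1.86 and Dlx1 with 1.73. The other lists called were muscle with 1.17 (adjusted p = 0.652 with an estimated correlation), glia with 0.55, maxillary identity with 0.56 and eye and forebrain with 0.31 (each adjusted p = 0.471 with an estimated correlation). Hypoxia genes had 0.11 (adjusted p = 0.577 with an estimated correlation) and erythroid genes -0.38 (adjusted p = 0.652 with an estimated correlation). Without knockout maxilla distal 1 the medians were 0.38 for muscle, 0.05 for hypoxia and -0.12 for erythroid genes. Erythroid genes had -0.70 without knockout maxilla distal 2, and without knockout maxilla distal 3 muscle genes had 1.90, eye and forebrain genes 0.49 and Dlx1 2.64. In each of these 7 lists 0 genes passed adjusted over the list alone or over all genes (limma, with 395 of all genes at an unadjusted p under 0.05). Limma called 0 genes without control maxilla distal 1, 2 or 3 or knockout maxilla distal 1 (449, 477, 261 and 216 unadjusted), 8 without knockout maxilla distal 3 and 1 without knockout mandible distal 2. Centring array medians left 1 gene higher and 0 lower, and a fit of only these 2 groups called 0 (limma, 342 unadjusted). Without the arrays with Y-linked signal 0 were called (427 unadjusted), without the doubted ends and the neuron-rich arrays 5, and with array weights 14.

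In maxilla proximal, 483 genes were higher and 376 lower in knockouts. Ppp1r1c rose by at least 5.58 (SE 0.51, adjusted p = 2.25e-05), from 5.80 ± 0.14 to 11.38 ± 1.62, and Pou4f1 by at least 5.09 (SE 0.48, adjusted p = 2.25e-05), from 5.31 ± 0.10 to 10.40 ± 1.65, both from control values at background. Ppp1r17 rose by 4.72 and Sncg by 4.65. Elf5, an epithelial factor, fell by 3.74 (SE 0.72, adjusted p = 0.0127), from 10.74 ± 0.18 in controls, and its SD in knockouts was 2.39. Also lower were Atp8b4 (-3.61), the sulfotransferase gene Sult1e1 (-3.56) and Sp8, a factor of facial ectoderm (-3.34). Neuron genes rose as a list with a median of 1.79 and 14 of 14 positive (adjusted p = 0.351 with an estimated correlation), with 8 higher over all genes, such as Nefm (4.27), Nefl (3.90), Prph (3.40) and Isl1 (2.31), and 13 adjusted over the list alone. Muscle genes had a median of 2.90 (adjusted p = 0.681 with an estimated correlation), with Myh3 (4.10), Tnnt2 (3.70), Myh8, Mylpf and Tnni1 higher over all genes. Adjusted over the list alone, 16 muscle genes were higher and Pax7, a gene of muscle stem cells and neural crest, was lower (-1.79). Epithelial genes had -1.38 (adjusted p = 0.681 with an estimated correlation), with 8 lower over all genes and 8 adjusted over the list alone, such as Krt8 (-2.19), Cldn7 (-2.09), Epcam (-1.59) and Cdh1 (-1.58). Glial genes had 0.77 (adjusted p = 0.680 with an estimated correlation), with Fabp7 (3.16), Cdh19 (1.53) and Foxd3 (1.05) higher over all genes and 4 adjusted over the list alone. Macrophage genes had 0.66 (adjusted p = 0.681 with an estimated correlation), with Ctss (1.03) higher over all genes and 8 adjusted over the list alone. Wnt genes had -0.50 (adjusted p = 0.681 with an estimated correlation), with the antagonist Dkk1 (-1.76) and Rnf43 (-1.08) lower over all genes and 6 adjusted over the list alone. Cell cycle genes had -0.22, with E2f1 (-0.29) lower over all genes and 3 adjusted over the list alone, and BMP genes had -0.20 (both adjusted p = 0.681 with an estimated correlation).

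The 3 knockout maxilla proximal arrays were unlike each other. Their neuron scores, the mean deviation of the list from the mean of all arrays, were 3.27, 3.02 and 1.31 for arrays 1, 2 and 3, against -0.01, 0.25 and 0.25 in the controls. The epithelium scores were -1.62, -1.62 and 0.12, the muscle scores 1.91, 0.54 and -0.66 and the glia scores 1.43, 1.02 and 0.36. The glia median was 0.48 and the cell cycle median -0.11 without array 1, and the BMP median was -0.35 without array 3. The count of 859 was 36 without knockout array 1, 19 without array 2 and 3366 without array 3. It was 25, 101 and 103 without control arrays 1, 2 and 3. Without the 2 most neuron-rich arrays, knockout arrays 1 and 2, the group is 1 array and the spread comes from the other groups alone. That fit called 7 genes, among them Ppp1r1c (3.72), Pou4f1 (3.18), Sncg (2.98) and Prrxl1 (2.13). Without the 4 arrays with doubted ends 15 genes were called, and 6 without both sets, again with 1 knockout array. A fit of only these 2 groups called 0 genes (limma, 2290 unadjusted), and 17 were called without the arrays with Y-linked signal. Cyclic loess scaling gave 599 higher and 286 lower, and array weights gave 3245 genes.

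**Figure D2:**
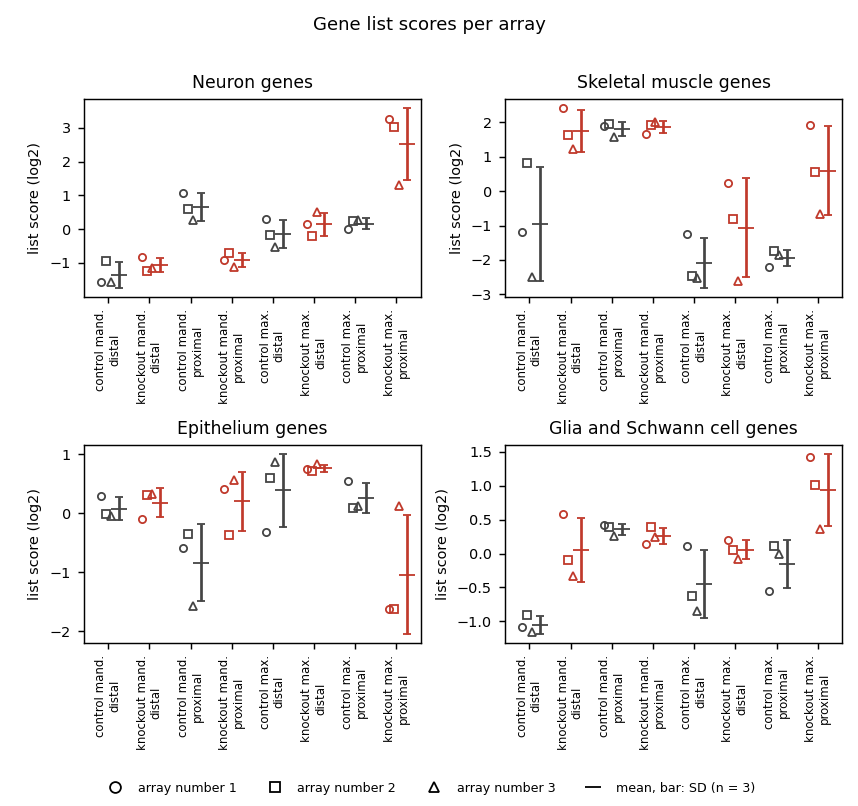
Score of the neuron, muscle, epithelium and glia lists on each array (vertical axis, mean log2 deviation of the list's genes from their mean over the 24 arrays) in the 8 groups (horizontal axis), with circles, squares and triangles for arrays 1, 2 and 3 and bars for the mean ± SD (n = 3). The neuron score is 3.27, 3.02 and 1.31 in knockout maxilla proximal and -0.92 ± 0.22 in knockout mandible proximal.

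Whether the genotypes differed in the same way in both jaws and at both ends was tested directly. The genotype effect differed between mandible and maxilla for 5 genes, all with a lower effect in the mandible: Pou4f1 by -4.38 (SE 0.48, adjusted p = 0.00045), Ppp1r1c by -4.38 (SE 0.51, adjusted p = 0.000526), Ppp1r17 by -3.90, Prrxl1, a factor of sensory neurons, by -3.14 and Sncg by -3.13. Pou4f1 differed between genotypes by -0.35 in mandible distal, -3.07 in mandible proximal, 0.26 in maxilla distal and 5.09 in maxilla proximal. All 5 genes were called in each fit that left out 1 array, while the count rose to 8 without knockout maxilla distal 3 and to 529 without knockout maxilla proximal 3. Without the 4 arrays with doubted ends, and likewise without the 4 with Y-linked signal, 2 genes were called, while 18 were called without the neuron-rich arrays and 640 with array weights. The neuron list was called, with a median of -1.77 and 0 of 14 positive, and stayed called with an estimated correlation (adjusted p = 0.0264). In it 2 genes passed over all genes and 14 adjusted over the list alone. Epithelial genes had 1.06 (adjusted p = 0.383 with an estimated correlation), FGF genes 0.18 and immediate early genes 0.15 (both adjusted p = 0.796 with an estimated correlation).

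For the difference of the genotype effect between the ends limma called 1 gene, Stk32a, at 0.50 (SE 0.074, adjusted p = 0.0316). Its values lay between 5.14 and 6.02 on all arrays and above the 30th percentile of the array in the 3 knockout maxilla distal arrays alone, so the call rests on values near background. Lists called were proximal jaw (0.65), maxillary identity (0.48), muscle (0.47), eye and forebrain (0.41), FGF (0.18) and cell cycle (0.08). With an estimated correlation these had adjusted p = 0.217, 0.294, 0.763, 0.616, 0.726 and 0.726. Limma called 0 genes in 16 of the 24 fits that left out 1 array, with 436 to 804 genes at an unadjusted p under 0.05. These were the fits without control maxilla proximal 1, 2 or 3, control maxilla distal 2 or 3, control mandible distal 3, control mandible proximal 2 or 3, knockout mandible distal 1 or 2, knockout mandible proximal 1, 2 or 3, knockout maxilla distal 2 or 3 and knockout maxilla proximal 1. It called 173 genes without knockout maxilla proximal 3, and 0 without the 4 arrays with doubted ends (556 unadjusted).

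The comparison of control mandible with control maxilla gives the expression that sets the jaws apart. Here 2407 genes were higher in the mandible and 2190 in the maxilla. Hand2, a factor that specifies the lower jaw, was higher in the mandible by 7.05 (SE 0.50, adjusted p = 1.29e-07), with 13.55 ± 0.04 in mandible distal and 5.44 ± 0.37, a level at background, in maxilla distal. Mymx, which encodes a protein of myoblast fusion, was higher by 4.01 and Gpr50 by 3.94, followed by the muscle genes Actc1 (3.84), Myh3 (3.77), Tnnt2 (3.70) and Myl4 (3.69), then Cbln4 (3.63), Ttn (3.60) and Myog (3.36). Higher in the maxilla were Fstl5 (-5.92, SE 0.42), the head patterning gene Otx2 (-5.77, SE 0.47, adjusted p = 7.29e-07), Sp8 (-5.36) and Lhx2 (-5.07), then Uncx (-4.90), Elf5 (-4.64), Fezf1 (-4.61), Dmrt3 (-4.40), Sult1e1 (-4.31) and Olig1 (-4.30). Otx2 had 10.27 ± 0.16 in maxilla distal and 4.21 ± 0.34, a level at background, in mandible distal.

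Of the list of mandibular identity, 9 of 11 genes were higher in the mandible, over all genes and adjusted over the list alone, with a median of 1.23 and a call that held with an estimated correlation (adjusted p = 0.00837). Examples were Pitx1 (2.49, SE 0.35), Dlx6 (1.56), Gbx2 (1.47) and Dlx5 (1.23). Genes of the proximal jaw had a median of 1.41 (adjusted p = 0.196 with an estimated correlation), with 8 higher, such as Dlx1 (2.25), Dlx2 (2.15) and Lhx8 (1.64). Muscle genes had 2.78 (adjusted p = 0.716 with an estimated correlation), with 16 higher over all genes, 17 adjusted over the list alone, and Pax7 lower (-3.40). Hox genes had 0.55 (adjusted p = 0.850 with an estimated correlation), with 3 higher over all genes, Hoxa2 (3.00), Hoxb2 (1.46) and Hoxa3 (0.37), and 6 adjusted over the list alone. Epithelial genes had -0.80 (adjusted p = 0.864 with an estimated correlation), with 8 lower, such as Krt8 (-2.88) and Krt18 (-2.57), and 1 higher, Krt15 (1.38). Adjusted over the list alone 2 were higher and 8 lower. Eye and forebrain genes had -0.45 (adjusted p = 0.305 with an estimated correlation), with 5 lower, such as Neurod1 (-3.56), Pax6 (-3.04) and Six3 (-2.37). Targets of p53 had -0.11 (adjusted p = 0.0811 with an estimated correlation), with 5 lower over all genes and 7 adjusted over the list alone, such as Pmaip1 (-2.32) and Sesn2 (-0.43). Other lists were not called but held genes that passed over all genes. Among neuron genes Ina (-2.32) and Elavl3 (-2.27) were higher in the maxilla and Pou4f1 (1.77) and Nefm (1.41) in the mandible. Foxl2 (-2.12), Nr2f1 (-1.18), Alx1 (-3.24), Id4 (-1.54), Six2 (-1.37) and the cartilage factors Sox5 (-1.08) and Sox9 (-0.89) were higher in the maxilla. Thbs4 (2.39), Acta2 (1.91), Cyp26a1 (0.83) and Smad2 (0.56) were higher in the mandible. The 4597 genes became 2154 without the arrays with Y-linked signal, of which 2140 were shared, and centring array medians gave 3265 higher and 1574 lower. No single array moved the count beyond 3542 to 4902.

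**Figure D3:**
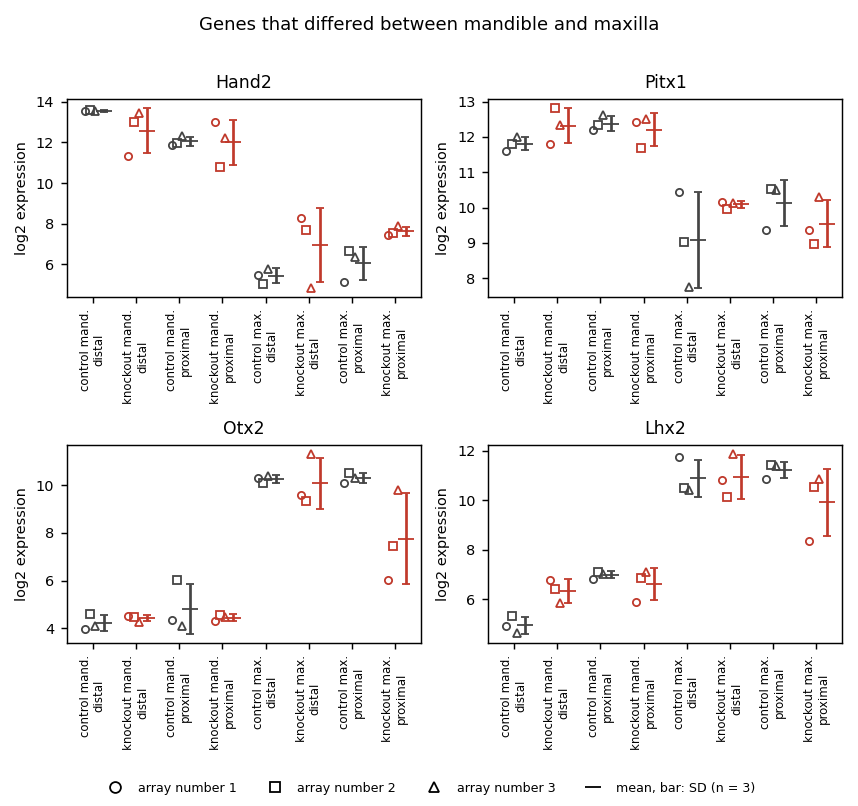
Log2 value of Hand2, Pitx1, Otx2 and Lhx2 on each array (vertical axis) in the 8 groups (horizontal axis), controls in grey and knockouts in red, with circles, squares and triangles for arrays 1, 2 and 3 and bars for the mean ± SD (n = 3). In controls Hand2 has 13.55 ± 0.04 in mandible distal and 5.44 ± 0.37 in maxilla distal, and Otx2 has 4.21 ± 0.34 and 10.27 ± 0.16.

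Along the control mandible, 165 genes were higher at the distal and 348 at the proximal end. Alx1 was higher distally by 5.99 (SE 1.1, adjusted p = 0.0115), with 12.56 ± 0.19 against 6.56 ± 0.48. It was followed by the heparanase gene Hpse2 (3.21), Dlg2 (2.93), the prostaglandin receptor gene Ptger2 (2.49), Aldh1a7 (2.48), Sgms2 (2.44), Insyn2b (2.20), Hpgd (2.15), Cited1 (2.13) and Dkk1 (2.11). Higher proximally were the antisense transcript Dlx1as (-5.78, SE 0.99), Hoxd1 (-5.20), Hoxa2 (-4.81), Sim2 (-4.42) and the neurofilament genes Nefm (-4.17, SE 0.70) and Nefl (-4.00). They were followed by Nr2f1 (-3.73, SE 0.48, adjusted p = 0.00209), Neurod1 (-3.46), 3110099E03Rik (-3.43) and Fabp7 (-3.42).

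Of 28 lists 14 were called along the control mandible, and none with an estimated correlation. Genes of the distal jaw were higher distally with a median of 1.51 (adjusted p = 0.105 with an estimated correlation), with 4 over all genes, such as Bmp4 (1.78) and Alx4 (1.51), and 5 adjusted over the list alone. BMP genes had 0.42 (adjusted p = 0.206 with an estimated correlation), with 3 higher, such as Bambi (1.66), and Bmper lower (-2.07), while 7 were higher and 2 lower adjusted over the list alone. Wnt genes had 0.63 and epithelial genes 1.04 (both adjusted p = 0.282 with an estimated correlation), hypoxia genes 0.08 (adjusted p = 0.375 with an estimated correlation) and erythroid genes 0.42 (adjusted p = 0.686 with an estimated correlation). The epithelium scores of arrays 1, 2 and 3 were 0.30, -0.004 and -0.05 distally and -0.58, -0.35 and -1.58 proximally, so proximal array 3 was the lowest. The erythroid scores of arrays 1, 2 and 3 were 0.13, 0.12 and 0.97 distally and -0.23, -0.22 and 0.63 proximally. Array 3 was thus higher at both ends, and the distal score exceeded the proximal by a similar amount at each number. The unpaired test does not use this likeness of arrays with the same number. Muscle genes were higher proximally with -2.83 (adjusted p = 0.191 with an estimated correlation), with 7 over all genes and 18 adjusted over the list alone. Neuron genes had -2.15 (adjusted p = 0.155 with an estimated correlation) with 9 on both counts, and glial genes -1.09 (adjusted p = 0.105 with an estimated correlation) with 5 on both counts. Genes of maxillary identity had -1.46 (adjusted p = 0.0649 with an estimated correlation), with 5 over all genes and 7 adjusted over the list alone, such as Shox2 (-2.28) and Nr2f2 (-1.90). Genes of the proximal jaw had -0.67 (adjusted p = 0.155 with an estimated correlation), with 3 over all genes, Barx1 (-2.70), Dlx1 (-2.42) and Meis1 (-1.82), and 4 adjusted over the list alone. Hox genes had -0.93 (adjusted p = 0.259 with an estimated correlation), eye and forebrain genes -0.53 and immediate early genes -0.34 (both adjusted p = 0.191 with an estimated correlation), the last with Jun (-1.43) and Egr1 (-1.38). The count of 513 was 57, 90 and 120 without control mandible proximal 1, 2 and 3. It was 116 and 61 without control mandible distal 1 and 3, 859 without knockout maxilla proximal 3 and 27 without the arrays with Y-linked signal, all 27 shared with the 513. Without the 4 arrays with doubted ends it was 985, without the neuron-rich arrays 960, without both sets 1739, with array weights 2504 and in a fit of only these groups 1439.

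**Figure D4:**
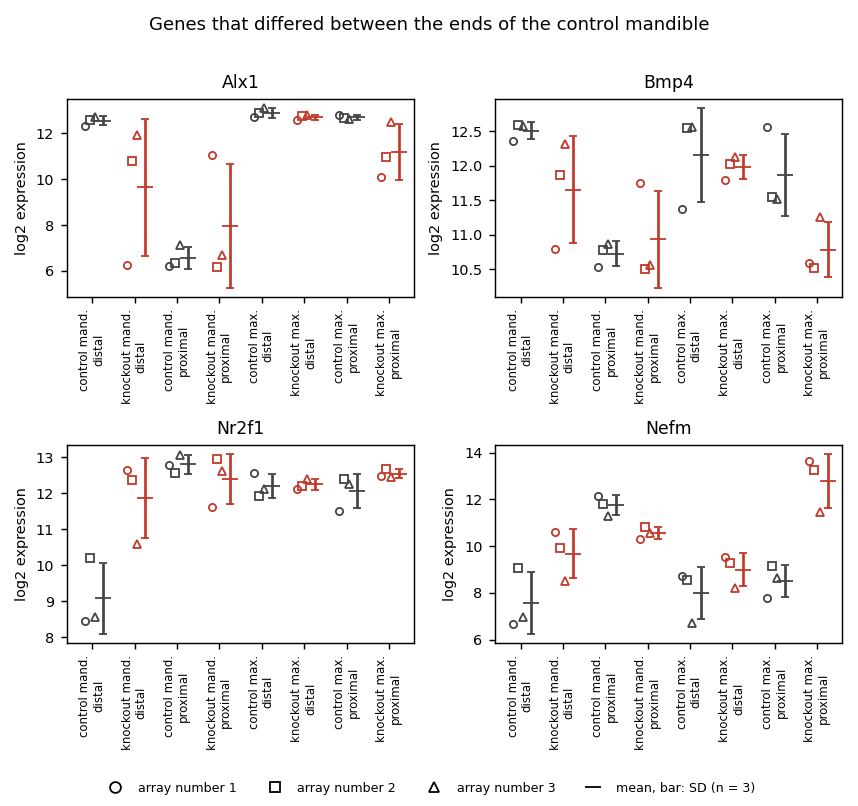
Log2 value of Alx1, Bmp4, Nr2f1 and Nefm on each array (vertical axis) in the 8 groups (horizontal axis), controls in grey and knockouts in red, with circles, squares and triangles for arrays 1, 2 and 3 and bars for the mean ± SD (n = 3). In the control mandible Alx1 has 12.56 ± 0.19 distally and 6.56 ± 0.48 proximally, and Nefm has 7.58 ± 1.31 and 11.75 ± 0.42.

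Along the control maxilla, limma called 0 genes, and 103 had an unadjusted p under 0.05. Genes of the proximal jaw were higher proximally as a list, with a median of -0.88 and 0 of 11 positive, and stayed called with an estimated correlation (adjusted p = 0.0177), among them Lhx6 (-1.91) and Barx1 (-1.51). BMP genes were called with a median of 0.06 (adjusted p = 0.948 with an estimated correlation). The smallest p-values, none of which passed, were those of Bmp2 (0.68), Frzb (-0.82), Dhh (-0.33), Gm31513 (-0.32) and Wfdc17 (-0.22). Without the 4 arrays with doubted ends, which leaves 2 arrays for each end of the control maxilla, 104 genes were called. The arrays left out were chosen because they ran against the difference of the ends, so that count is no independent evidence of it. Array weights gave 34.

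Whether the ends differed in the same way in both control jaws was tested as a difference of differences. Limma called 0 genes (920 unadjusted). Nr2f1 had the smallest p-value, with -3.87 (SE 0.68, adjusted p = 0.264). The lists called numbered 13, and none with an estimated correlation, among them muscle (-2.63, adjusted p = 0.164 with an estimated correlation), neuron (-1.91, adjusted p = 0.164 with an estimated correlation), maxillary identity (-1.18, adjusted p = 0.0701 with an estimated correlation) and distal jaw genes (1.30, adjusted p = 0.0905 with an estimated correlation). The count was 1 without knockout mandible distal 1, control mandible distal 2, knockout mandible proximal 2 or knockout mandible distal 3, 8 without knockout maxilla proximal 3 and 35 without the 4 arrays with doubted ends. It was 394 with array weights, 242 in a fit of only these groups, and 127 without both the arrays with doubted ends and the neuron-rich arrays. Averaged over both control jaws, 14 lists were called, and genes of maxillary identity (-0.90) and of the proximal jaw (-0.81) stayed called with an estimated correlation (both adjusted p = 0.0459).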

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

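The splits of the arrays were planned, while the tests on neuron, muscle and epithelium genes were chosen, and in part replaced, only after the result was seen. A difference between groups singled out 5 genes whose genotype effect differed between mandible and maxilla by limma's test of the difference. These were Pou4f1 (-4.38), Ppp1r1c (-4.38), Ppp1r17 (-3.90), Prrxl1 (-3.14) and Sncg (-3.13), each with a negative change in mandible proximal and a positive one in maxilla proximal. All 5 passed in maxilla proximal, but only Pou4f1 and Ppp1r1c passed in mandible proximal. Of 100 splits of the genotype labels, the real one included, 2 gave at least 5 genes, which excludes chance only if the arrays are independent, and the highest other split gave 429 genes and points to a structure of the samples. Without the 6 arrays in doubt they had -3.41 (Pou4f1), -3.50 (Ppp1r1c), -3.02 (Ppp1r17), -2.16 (Prrxl1) and -2.27 (Sncg) and were called, but that fit has a single knockout maxilla proximal array, number 3, and takes its spread from other groups. A difference between the ends singled out 1 gene, Stk32a (0.50), whose values lie near background, and 4 of 100 splits gave at least 1 gene, with 3 in the highest other split.

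Knockout maxilla proximal arrays 1 and 2 had more signal from neuron and muscle genes and less from epithelial genes. Array 3 had a neuron score of 1.31 and a muscle score of -0.66, both above every control maxilla proximal array (at most 0.25 and -1.74). Its epithelium score of 0.12 lay within those controls. A rise of neuron genes with the genotype in every region is argued against by their median of -1.23 in mandible proximal, which was known when the test was chosen. A separate list of sensory ganglion genes had a median of -0.14 there, with 5 of 11 positive and 0 called lower, so it adds little. A lower share of mesenchyme that raises all other cell types alike is excluded for arrays 1 and 2 by epithelium scores of -1.62 each, and for array 3 (0.12) it stays open. Sensory ganglion tissue with no other nervous tissue is a candidate explanation for array 1 (score 2.02 for sensory ganglion genes, -0.21 for central nervous system genes) but not for array 2 (1.16 and 2.32, against at most 0.61 for central genes in control maxilla proximal), and an earlier test that pooled the 3 arrays had given medians of 1.35 and 0.17. Tissue at the edge of the dissection and an effect of genotype on where ganglia lie both stay open, since the spread is among the 3 arrays of 1 group.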

How the results depend on the processing

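The alternatives that leave out sets of arrays were chosen after the data were seen, and the others were planned. Of the values of named genes, 2877 kept their direction and side of the threshold under alternatives other than leaving out 1 array, 333 became weaker, 23 stronger and 1 reversed. With 1 array left out, 4424 kept both, 776 became weaker and 8 stronger. The reversed value was Mpg in mandible proximal, which had -0.0086 as the mean of all its probe sets. The cause of a change was not tested unless stated; fewer genes tested, fewer arrays or a fold threshold change a count by construction. Weak signal near background limits what the arrays can show for genes of low expression.

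For knockout against control as the mean over the regions, 70 genes became 164 with cyclic loess, 258 with the filter at the 50th percentile and 192 with the trend and robust prior. Array weights gave 2906, a fold threshold 10, and leaving out 1 array 6 to 2132. It was 23 without the 4 arrays with doubted ends, 8 without the 2 neuron-rich arrays, 15 without these 6 and 20 without the 4 arrays with Y-linked signal. Without the neuron-rich arrays, and without the 6, knockout maxilla proximal is 1 array. Tgfbr2 kept its direction, from 0.27 to 0.39 with 1 array left out, and passed the threshold with array weights (0.27, adjusted p = 0.0276).

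In mandible distal, array weights gave 642, a fold threshold 10, only the groups compared 0 (limma, 1437 unadjusted), and leaving out 1 array 0 to 258. Leaving out the sets of arrays in the same order gave 13, 62, 31 and 54. In mandible proximal, array weights gave 294, a fold threshold 4, only the groups compared 0 (670 unadjusted), and leaving out 1 array 0 to 28. It was 2 without the 4 arrays with doubted ends, 31 without the neuron-rich arrays and 0 without the Y-expressing arrays (363 unadjusted). In maxilla distal, 1 gene was called with medians centred, with the mean of all probe sets and with all probe sets singly, 14 with array weights, 0 with a fold threshold (22 unadjusted), 0 with only the groups compared (342 unadjusted), 5 without the 6 arrays, 0 without the Y-expressing arrays (427 unadjusted), and 0 to 8 with 1 array left out. In maxilla proximal, array weights gave 3245, a fold threshold 348, only the groups compared 0 (2290 unadjusted), and leaving out 1 array 19 to 3366. The sets of arrays gave 15, 7, 6 and 17.

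For the genotype effect between jaws, array weights gave 640, leaving out 1 array 5 to 529, and the sets of arrays 2 without those with doubted ends, 18 without the neuron-rich and 2 without the Y-expressing ones. Between ends, array weights gave 21, leaving out 1 array 0 to 173, and limma called 0 with medians centred (526 unadjusted), cyclic loess (592), the filter at the 50th percentile (512), all probe sets singly (840), a fold threshold (45) and without each of the sets of arrays (556, 441, 602 and 444).

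Mandible against maxilla in controls gave 545 with a fold threshold, 2154 without the Y-expressing arrays and 3542 to 4902 with 1 array left out. Along the control mandible, array weights gave 2504, a fold threshold 274, only the groups compared 1439, leaving out 1 array 57 to 859, and the sets of arrays 985, 960, 1739 and 27. Along the control maxilla, array weights gave 34, and 104 and 224 genes were called without the 4 and the 6 arrays. The difference between jaws gave 394 with array weights, 242 with only the groups compared, 0 to 8 with 1 array left out, and 35, 10 and 127 without the 4, the 2 and the 6 arrays.

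The array number was also used as a replicate block, though the correlations did not settle whether the numbers pair arrays. Of 36 pairs of the same genotype and number 23 had a correlation of deviations over 0.1, with a median of 0.15. Of 36 pairs of the same number with another genotype and region 15 did, with a median of 0.03. Of 12 pairs of the same region and number across genotypes 5 did. The lowest correlation, -0.65, was between the ends of control maxilla 1, whose labels are in doubt. Arrays of 1 set do share some signal, as the Y-linked genes of control number 2 and the low erythroid scores of knockout number 1 show. As a fixed block it gave 1102 genes for the mean over the regions, 66 in mandible distal, 1717 in maxilla proximal, and Tgfbr2 at 0.34 (adjusted p = 0.0277). With genotype and number as a random block (consensus correlation 0.158) the mean over the regions gave 6 genes, the genotype effect between jaws 8 and the control mandible 924. The block of 6 means gave 0 genes (limma, 1595 unadjusted).

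The 9 lists called for the mean over the regions became 0 with an estimated correlation, 4 by fry (muscle, glia, maxillary identity and immediate early genes) and 7 to 12 with 1 array left out. The 7 lists of the jaw comparison became 1 with an estimated correlation, and 6 to 8 with 1 array left out. The 14 lists of the ends in controls became 2 with an estimated correlation, 6 by fry, and 13 to 15 with 1 array left out.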

Other observations

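The splits of the arrays were planned, while the tests on the ends and on the genes called over the regions, and the fits without sets of arrays, were chosen only after the result was seen. With all arrays limma called 0 genes between the ends of the control maxilla (103 unadjusted). Without the 6 arrays in doubt, which leaves 2 arrays for each end, it called 224, but control maxilla proximal 1 and distal 1 were left out because they ran against the difference of the ends, so these values are no independent evidence of it. In that fit Fgf8, a growth factor of facial ectoderm, had 3.05, Msx2 2.08 and the neurotensin gene Nts 2.86, with positive values higher distally, while Vtn, which encodes vitronectin, had -5.20, Zic1 -3.64 and Zic2 -3.27. The difference of the ends between the jaws was called for 127 genes, with Alx1 at 5.64, Vtn at 4.88 and Dlx4 at -2.98, under the same limit.

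The ends of control maxilla 1 and knockout mandible 1 looked exchanged. On 100 genes picked from the other 5 pairs of the jaw, the distal minus proximal score was -1.314 in control maxilla 1 (others at most 0.36, median 0.25) and -1.154 in knockout mandible 1 (others at most 0.53, median 0.36). An exchange of the end labels is a candidate explanation for both. Sizes of 1.314 and 1.154 argue against ends that hardly differ. These pairs were picked because their arrays ran against their labels, so the scores are no independent test of either. For control maxilla 1 the gene lists were divided. Its proximal jaw score ran as labelled, with -0.69 in the proximal and -1.33 in the distal array. Its distal jaw score ran against the labels, with 0.15 in the proximal and -0.77 in the distal array. The scores of the other pairs are lowered because their genes were picked with the doubted pair included. An effect of genotype on the ends of the mandible stays open, since the other knockout mandible pairs had -0.031 and 0.25.

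Of the 70 genes called over the regions, 58 moved the same way in all 4 regions and 6 were called in every fit that left out 1 array. The sex of the embryos is argued against as the whole cause of the 70, since without the 4 arrays with Y-linked signal the 70 genes kept their direction and had a median ratio of 1.06 to the change with them. Variants among the 100 neighbours on each side of the engineered genes are excluded as the cause of all 70. Of the called genes with a position, 66 lie outside these neighbours. Among the 344 neighbours 3 were called (odds ratio 1.92, one-sided Fisher exact p = 0.215). All 3 were among the 167 neighbours of H2az2 and none among the 177 of Tgfbr2, and the 2 places were not tested singly. That test cannot exclude linked variants as the cause for some of the genes, nor variants further from the engineered genes. The Wnt1-Cre transgene is known to be inserted at H2az2, which may account for H2az2 itself (-0.57), but the neighbours called, Vrk2 (-0.33), Acyp2 (0.44) and Mpg (0.39), keep open whether it acts on H2az2 alone. Strain variants elsewhere, an effect of the transgene on distant genes and an effect of the genotype stay open, and none was tested.

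Other splits of the arrays gave these counts, with the real split included. For the mean over the regions 2 of 100 splits gave at least 70 genes, which excludes chance only if the arrays are independent. The highest other gave 1032, which points to a structure of the samples. With whole numbers kept together 2 of 10 splits did, and control 1, control 3 and knockout 3 against the rest gave 265, but 10 splits are too few for a share under 0.05. For mandible against maxilla 1 of 100 splits gave at least 4597, with 1517 in the highest other, which excludes chance if the arrays are independent. For the difference of the ends between jaws the real count was 0 (limma, 920 unadjusted), which all 100 splits reach by construction, so this count says nothing about chance. The highest other split there gave 1468, which points to a structure of the samples. In comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. There the real split gave 20, 8 and 3 genes in mandible distal, mandible proximal and maxilla distal, and 513 along the control mandible, with 0 in the highest other (limma), and it gave 859 in maxilla proximal with 41 in the highest other. Each of these 5 counts was reached by 1 of the 10 splits. Along the control maxilla the real split gave 0 genes (limma, 103 unadjusted), which all 10 splits likewise reach by construction, with 390 for the split that exchanges the ends of array 1.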
